A study of Mus musculus with 3 samples.

How the data were processed

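Sp9, a zinc finger transcription factor, was immunoprecipitated from crosslinked chromatin of mouse olfactory bulbs, and the recovered DNA was sequenced. Per the labels' protocols, the bulbs came from CD1 mice on postnatal days 0 to 2. Crosslinking used 1% formaldehyde and took 10 min, and shearing gave fragments of 200 to 1000 bp. The antibody against Sp9 was homemade. Libraries were read as paired ends of 150 bases. There were 2 Sp9 immunoprecipitation libraries and 1 input library without antibody, as the labels' titles give them. Whether the 2 immunoprecipitations came from separate litters or from 1 pool of bulbs is not given in the sources used here.

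The single file analysed is a list of peaks that the authors named as shared. Each line holds a chromosome, a start, an end, a peak score and 1 gene name. Bowtie2 2.2.4, MACS 1.4.2 and the mouse build mm9 are named in the submitters' processing notes, which give neither their roles nor their settings. Bowtie2 is a read aligner and MACS a peak caller. The rule by which a peak counted as shared, the way 1 interval and 1 score were taken from 2 libraries, the formula of the score and the gene annotation are not given in the sources used here. The deposited peak score is 1 value per peak and names no library, so it was used only to rank and filter peaks within the list. The deposited positions (start and end, which are neither counts nor a signal) are printed as the list gives them, and whether starts count from 0 or from 1 is not stated. The numbers of reads, the tags per peak and the fold over input were not analysed here, so the depth of each library is unknown and no interval for a single peak can be given.

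Gene names were matched to a RefSeq gene table of assembly GRCm38.p6, first by symbol and then by a synonym held by only 1 gene. Of 13383 distinct names, 12806 matched by symbol, 527 by synonym and 50 not at all; the unmatched names covered 89 peaks. Among the unmatched names, 18 had the form of a calendar date (37 peaks), the form that a spreadsheet gives to symbols of the septin and March families, and they were left out rather than guessed. No coordinate of that table was used, because the list is in another build; the table served for names, gene class and gene order. Of the placed peaks with a matched name, 99.8% lay on the chromosome of the named gene. Within each of 20 chromosomes the order of peaks followed the order of their genes, with a Spearman correlation across peaks of at least 0.998. A peak is called linked to the gene the authors named for it. The list gives no distance, and peaks with 1 name could lie more than 1 Mb apart, so a link does not place a peak at a promoter.

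Before the data were examined, 13 gene lists, the genes to be named and the tests were fixed. The lists were interneuron transcription factors, neuroblast migration and guidance, GABA and dopamine phenotype, pan-neuronal and synaptic genes, neural progenitor and cell cycle genes, mitral, tufted and other glutamatergic neurons, astrocytes and olfactory ensheathing glia, the oligodendrocyte lineage, microglia and vascular cells, ribosomal proteins and translation, chromatin and general transcription, mitochondrial respiration, and genes of other organs. For each list, the genes with at least 1 linked peak were compared with all other protein-coding genes of the table by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 13 lists and a threshold of 0.05. Intervals of shares are exact Clopper-Pearson intervals at 95%, and those of odds ratios are conditional exact intervals. Both treat genes as independent and describe this 1 list of peaks; genes are not biological replicates. Peaks with a score at or above the list's median are called above-median peaks. Tests between the interneuron transcription factors and each other list (Fisher's exact test, two-sided, adjusted over 12 comparisons, separately for any peak and for above-median peaks) were added after the values had been seen. The genes named are Sp8, Sp9, Prokr2 and Tshz1, the 20 peaks with the highest score, the 10 genes with the most linked peaks together with those tied with the last of them, and up to 4 members of each list with the highest scores. List members named beyond these, including members without a linked peak, were chosen after their values had been seen. Some list members that this rule would name are not reported here.

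The list test was checked on simulated links for all 21900 coding genes, in 100 draws per setting. A list of 28 genes at simulated odds of 3 was called in 28% of the draws, and at odds of 10 in 95%. With no list changed, 7 of 1200 tests of the other lists were called. Lists of this size therefore miss moderate differences often. Alternatives were above-median peaks only, the number of peaks per gene against 100000 random lists of the same size, and genes with a linked peak as the only background. Added after the data had been seen were 10000 random lists matched on the share of linked genes among 10 neighbouring coding genes, a background without predicted genes and the olfactory, vomeronasal and trace amine receptor families (18494 genes), and the list without unplaced peaks, ribosomal RNA names and runs of 5 or more peaks with gaps under 10 kb. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

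Several planned analyses could not be made from this list. The share of peaks at promoters and the content of GC-box and homeodomain motifs need an mm9 annotation and sequence, which were not used here. The agreement of the 2 immunoprecipitation libraries needs a value per library. A match on gene length was not made because the lengths at hand belong to another build.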

Results

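The study asked how the related zinc finger factors Sp8 and Sp9 act in the development of olfactory bulb interneurons, and this part of it mapped where Sp9 sat on chromatin in the neonatal bulb. Immunoprecipitation was run as 2 libraries against 1 input library, and the values available are those of the peaks shared between the immunoprecipitations. There is therefore no group comparison and no error between replicates for any peak. The list held 19979 peaks, of which 19880 lay on assembled chromosomes and 99 on unplaced or random sequences. Peaks had a median width of 986 bp (quartiles 784 and 1259 bp) and together covered 21.6 Mb. The authors' peak score ran from 80.01 to 3139.09 with a median of 210.06, and 222 peaks scored over 1000. Wider peaks had higher scores, with a Spearman correlation of 0.745 across peaks, which are not independent replicates.

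Most peaks, 17930 or 89.7%, carried the name of a protein-coding gene, 1228 that of a long non-coding RNA gene and 465 that of a microRNA gene. Of 21900 protein-coding genes, 12136 (55.4%) had at least 1 linked peak and 7763 (35.4%) an above-median peak. A single peak was linked to 8749 of these genes, and 281 genes had 5 or more. Of 13 gene lists fixed in advance, 8 were linked more often than other coding genes and 2 less often past the threshold. Among genes that had any linked peak, none of the 13 lists differed past the threshold in its share with an above-median peak (Fisher's exact test, adjusted p from 0.0626 to 1). Chromosome 12 had 115 peaks per 100 coding genes and chromosome 7 had 71.0, the highest and the lowest of the autosomes. Chromosome X had 789 peaks with a median score of 175, below the median of each of the 19 autosomes.

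The genes of the factor itself and of its partner were both among the linked genes. Sp9 had a peak of score 637.13 on chromosome 2 from 73110826 to 73113066 (mm9), above 93.9% of all peaks, and another of score 83.13 from 73115080 to 73116178. Sp8 had peaks of score 589.41 on chromosome 12 from 120086666 to 120088699 and of score 280.17 from 120074801 to 120075661. Tshz1, a zinc finger factor needed for the maturation of olfactory bulb neurons, had 1 peak of score 268.28 on chromosome 18 from 84254292 to 84255799, and a peak of score 617.89 directly beside it carried the name of the neighbouring gene Zadh2. Prokr2, the prokineticin receptor that guides neuroblasts into the bulb, had 1 peak of score 96.02 on chromosome 2 from 132210509 to 132211586, which lay above only 9.90% of all peaks. The list does not say whether these peaks fall in a promoter, exon, intron or between genes.

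**Figure D1:**
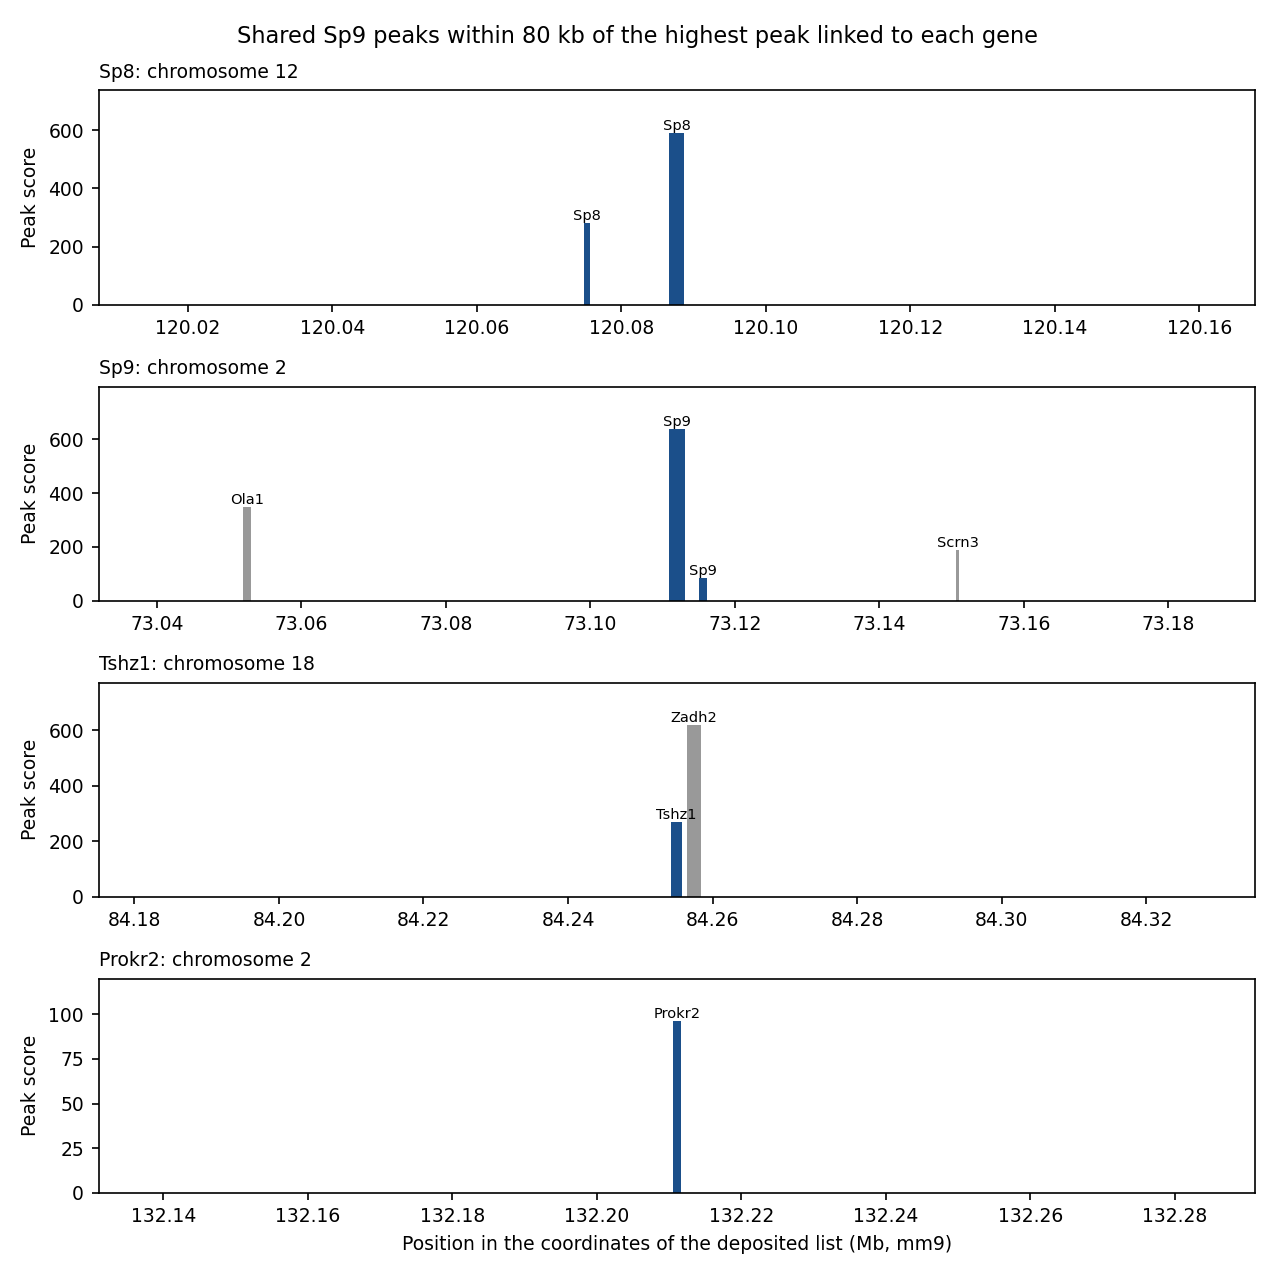
Shared Sp9 peaks within 80 kb of the highest peak linked to Sp8, Sp9, Tshz1 and Prokr2. The horizontal axis is the mm9 position in Mb, bar height the authors' peak score from 0 on a scale of its own in each panel, bar width the peak; blue bars carry the panel's gene name and grey bars that of another gene. The Prokr2 peak, at 96.02, is far lower than the highest Sp9 peak, at 637.13.

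Transcription factors of olfactory bulb interneurons were linked to Sp9 peaks without exception. All 28 genes of the list had a linked peak, against 55.4% of the other coding genes, and the 28 genes together had 74 peaks, or 2.64 per gene against 0.819 over all coding genes. High scores belonged to Sp4 (1116.63), Bcl11b, a zinc finger factor of GABAergic neurons (1090.42), and Sox11, a factor of immature neurons (923.06). Among the Dlx homeobox genes, which specify forebrain GABAergic neurons, the highest scores were 830.13 for Dlx2, 356.93 for Dlx1, 296.44 for Dlx5 and 261.47 for Dlx6. Etv1, with 92.19, had the lowest value when each gene was represented by its highest peak. The share of 100% had an exact interval from 87.7%, and the odds ratio was at least 5.72 by the lower bound of its interval (Fisher's exact test, adjusted p = 9.19e-07). Above-median peaks were linked to 25 of the 28 genes (89.3%). Among genes that had any linked peak, the share of 89.3% was not past the threshold against the 63.9% of other genes (Fisher's exact test, adjusted p = 0.0626, the highest of the 6 alternatives, whose lowest was 6.56e-08).

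Genes of neuroblast migration and guidance were linked nearly as often, with 26 of 28 (92.9%; odds ratio 10.5, interval 2.62 to 91.1, Fisher's exact test, adjusted p = 0.000154). Netrin 1 (Ntn1) had the highest score, 1241.88, followed by the doublecortin-like kinase Dclk1 with 928.62, the reelin receptor Lrp8 with 918.38 and neuregulin 1 (Nrg1) with 724. Dcx, the microtubule protein of migrating neuroblasts, had 2 peaks with a highest score of 134.69. Tnr and Sema3a had no linked peak. Neural progenitor and cell cycle genes had 23 of 25 linked (92%; adjusted p = 0.000409 by Fisher's exact test), led by the cyclin-dependent kinase inhibitor Cdkn1c (1376.16), cyclin E1 (Ccne1, 634.51), the Notch effector Hes5 (628.96) and Sox2 (583.79).

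Genes of the mature interneuron phenotype were not linked more often than other genes past the threshold. In the GABA and dopamine list, 17 of 25 genes (68%, exact interval 46.5 to 85.1%) had a linked peak (Fisher's exact test, adjusted p = 0.232). Tpbg, a marker of a granule cell type, scored 598.51, Gng4 542.36, neuropeptide Y (Npy) 520.63 and the GABA receptor subunit Gabra5 421.19. The enzymes of GABA synthesis had lower scores, 245.36 for Gad1 and 193.69 for Gad2. The dopamine synthesis genes Th and Ddc had no linked peak, while Gch1, which serves the cofactor of Th, and the vesicular monoamine transporter gene Slc18a2 had 1 each (217.99 and 127.3). The genes Vip, Sst, Synpr, Cck and Slc6a3 were also among those without a linked peak. The difference from the interneuron transcription factors was itself past the threshold: 28 of 28 against 17 of 25 for any peak (Fisher's exact test, adjusted p = 0.00488 over 12 comparisons), and 25 of 28 against 11 of 25 for above-median peaks (adjusted p = 0.00173). The GABA and dopamine list holds no transcription factors, so this contrast also sets regulators against other genes. Factors of other lineages, a list added later, had 31 of 34 linked to any peak and 18 of 34 to an above-median peak. Peaks per gene differed too, 2.64 against 1.32. Among genes with any linked peak, 64.7% of the GABA and dopamine list had an above-median peak, against 64.0% of other genes.

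Other neuronal lists lay above the background. Pan-neuronal and synaptic genes had 20 of 25 linked (80%; Fisher's exact test, adjusted p = 0.0213), with the neuronal nuclear protein Rbfox3 at 817.21, Elavl3 at 681.05 and Gphn at 486.89, while Snap25, Stx1a, Gap43, Ank3 and Scn2a1 had none. Genes of mitral, tufted and other glutamatergic neurons had 17 of 20 linked (85%; Fisher's exact test, adjusted p = 0.0126), led by Neurod2 (642.81), Emx1 (552.79), Neurog2 (534.39) and Lhx2 (514.56). Both calls were lost against named genes outside the receptor families (Fisher's exact test, adjusted p = 0.140 and 0.0988) and against lists matched on neighbouring genes (permutation test, adjusted p = 0.0832 and 0.103). Over the 6 alternatives their adjusted p from these exact and permutation tests ran from 0.0136 to 0.429 and from 0.00949 to 0.518.

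Glial lists did not pass the threshold, although their shares for any peak were close to the 80% of the pan-neuronal list. They hold fewer genes than that list, and neither was tested against the pan-neuronal or glutamatergic list. Astrocyte and olfactory ensheathing glia genes had 14 of 18 linked (77.8%, exact interval 52.4 to 93.6%; Fisher's exact test, adjusted p = 0.0719), among them Fgfr3 (915.89), Nfia (870.59), Glul (547.07) and Slc1a2 (432.79). The oligodendrocyte lineage had 12 of 15 (80%, exact interval 51.9 to 95.7%; Fisher's exact test, adjusted p = 0.0746), among them Olig2 (668.88), Olig1 (552.32), Ugt8a (371.88) and Pdgfra (318.73). Above-median peaks were linked to 7 of the 18 and 5 of the 15 genes. The interneuron factors exceeded both in above-median peaks (Fisher's exact test, adjusted p = 0.00152 and 0.000850), whereas for any peak they exceeded the astrocyte list (adjusted p = 0.0375) and not, past the threshold, the oligodendrocyte list (adjusted p = 0.0632).

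Markers of microglia and blood vessels, and genes of other organs, were linked less often than other coding genes. Of the microglial and vascular genes, 5 of 20 (25%) had a linked peak (odds ratio 0.268, interval 0.0761 to 0.776, Fisher's exact test, adjusted p = 0.0182). Of these, Flt1 (541.04), Cldn5 (353.27), Kdr (151.62) and Tek (101.99) are endothelial, and Tmem119 (82.96) is microglial. Of the genes of other organs, 4 of 26 (15.4%) had one (odds ratio 0.146, interval 0.0366 to 0.430, Fisher's exact test, adjusted p = 0.000154). They were the transthyretin gene Ttr, which is also active in the choroid plexus (3019.84, with 7 peaks), Ins1 (488.14), Apob (286.89) and Apoa1 (126.84). Counted as peaks per gene, the list had 0.462 against 0.819, which did not pass the threshold (permutation test against random lists, adjusted p = 0.0840, with 1.14e-05 to 1 over the alternatives), and 7 of its 12 peaks belonged to Ttr.

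Broadly active genes were also linked often. Chromatin and general transcription genes had 28 of 32 linked (87.5%; Fisher's exact test, adjusted p = 0.000490), with Yy1 (1181.57), Chd7 (1099.65), Arid1a (961.67) and Ctcf (888.74) the highest. Nuclear genes of mitochondrial respiration had 19 of 20 linked (95%; Fisher's exact test, adjusted p = 0.000409), but above-median peaks in only 7 (35%, against 35.4% of other genes), with Cox4i1 (908.50), Polg (712.52), Uqcrfs1 (488.55) and Cox5a (442.97) the highest. Ribosomal protein and translation genes had 19 of 24 linked (79.2%; Fisher's exact test, adjusted p = 0.0293), led by Rpl13 (550.17), Eif4a1 (509.92) and Eif3a (507.60). The call of the ribosomal list was lost with named genes as the only background (Fisher's exact test, adjusted p = 0.179, with 0.0437 to 0.620 over the alternatives), and counted as peaks per gene neither the ribosomal (0.958) nor the respiration list (1) passed the threshold. For any linked peak, the interneuron factors did not differ past the threshold from the chromatin list (28 of 28 against 28 of 32, Fisher's exact test, adjusted p = 0.154) or the respiration list (adjusted p = 0.455), but exceeded the ribosomal list (28 of 28 against 19 of 24, adjusted p = 0.0375). For above-median peaks they exceeded the respiration list (Fisher's exact test, adjusted p = 0.000531) and the ribosomal list (adjusted p = 0.0382) and not the chromatin list (adjusted p = 0.126). The number of peaks per gene, 2.64 for the interneuron factors, was 0.958 for ribosomal, 1 for respiration and 1.34 for chromatin genes. Among the other fixed lists, glutamatergic genes came closest with 2.25, followed by progenitor and cell cycle genes with 1.8.

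**Figure D2:**
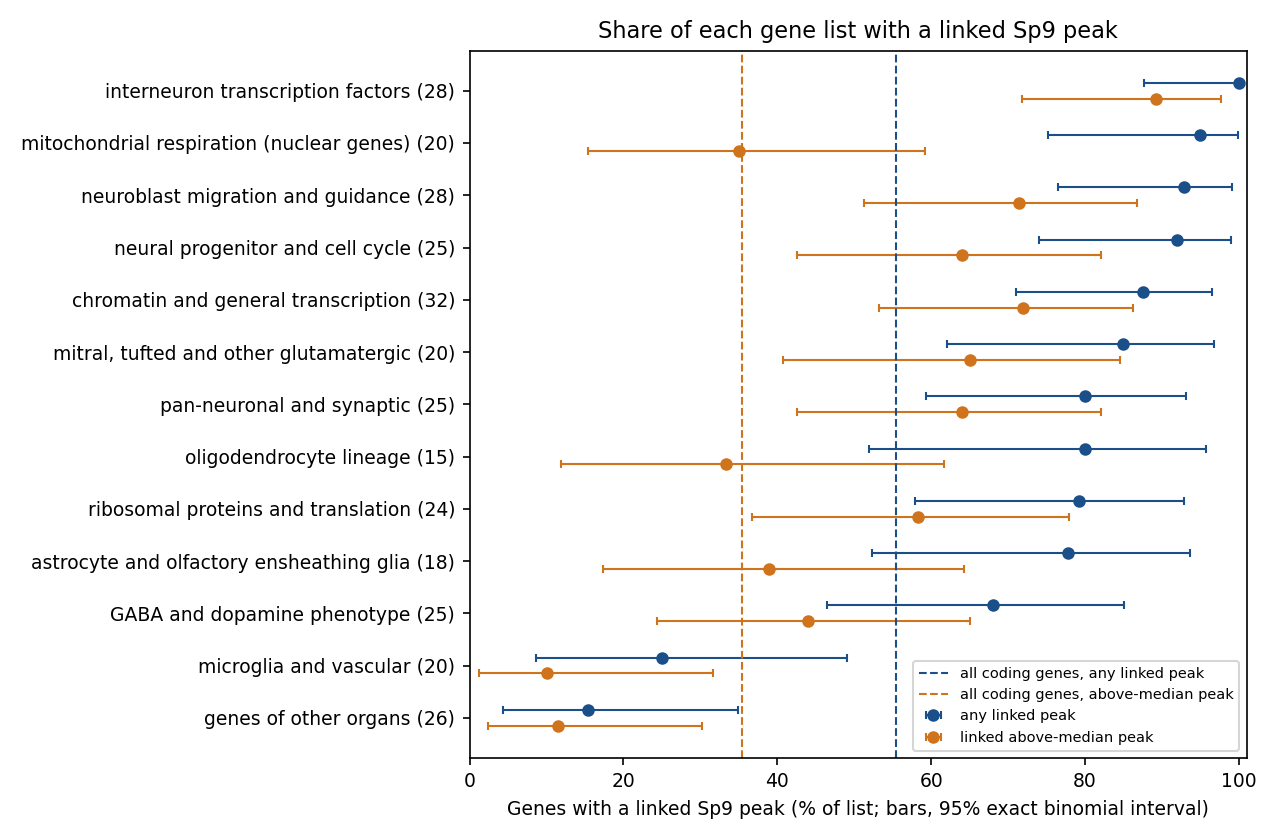
Share of each gene list with a linked Sp9 peak, in percent, for any peak (blue) and for above-median peaks (orange), with 95% exact binomial intervals over genes and the number of genes in brackets; dashed lines give the shares of all coding genes, 55.4% and 35.4%. Interneuron transcription factors reach 100% and 89.3%, while respiration genes reach 95% for any peak and 35% for above-median peaks.

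**Figure D3:**
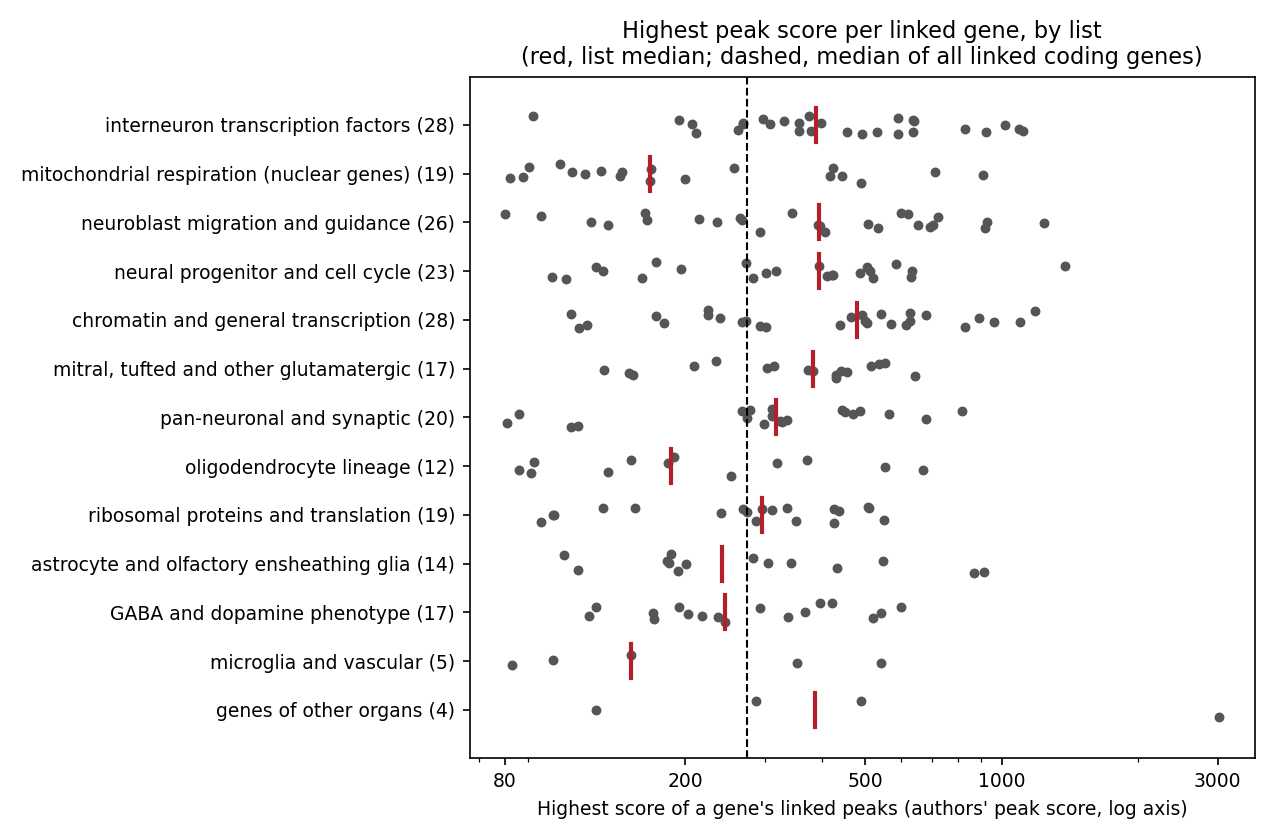
Highest score among a gene's linked peaks, on a log axis, with each dot a gene that has a linked peak (their number in brackets) and red bars the list medians; vertical jitter carries no meaning. The medians run from 152 for microglial and vascular genes to 478 for chromatin genes, against 273 for all linked coding genes (dashed). The median of 389 for interneuron transcription factors lies near those of migration (395), progenitor (394) and glutamatergic genes (383). It also lies near the 388 of genes of other organs, which rests on 4 linked genes. A gene with more peaks has more chances of a high value, and the lists differ in peaks per gene.

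Of the 20 highest peaks, only that of Ttr was linked to a gene of these lists. The peak with the highest score, 3139.09, carried the name of the vomeronasal receptor gene Vmn2r29 and lay on chromosome 7 from 7230320 to 7231307. The next 9 peaks all had a score of exactly 3100. Whether 3100 is a ceiling of the score is not given in the sources used here. Neither the order of these 9 peaks nor their place against the Vmn2r29 peak is therefore resolved. Of the 20 highest peaks, 8 were named for genes classed as ribosomal RNA and 1 for Rn45s, the ribosomal precursor gene, which the gene table did not match. Of these 8, 5 were named Gm25018 and 1 Gm22291, genes with the synonyms Rn5s10 and Rn5s30, and they lay between 126060913 and 126128259 on chromosome 8. The other 2 were named Rn4.5s, on chromosome 6. Names of coding genes were on 9 of the 20, namely Vmn2r29, Smgc (3100), Pld4 (2 peaks, 3100 and 3075.93), Ttr (3019.84), Pde1c (2651.95), Aga (2436.70), 4930467E23Rik (2214.28) and 9130204L05Rik (2193.32). The remaining 2 were named G530011O06Rik and Mir6546, each with a score of 3100.

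The gene with the most linked peaks was Atg7, an autophagy gene, with 33 peaks within 108 kb of chromosome 6. Gm16513 had 22 peaks, of which 21 lay on unplaced sequence, and all 19 peaks of Mucl2 did. Rn4.5s also had 19 peaks, 5730507C01Rik 13, and the cytoskeletal linker gene Plec 12, all within 61.3 kb of chromosome 15. Casz1, a zinc finger factor, and Tsn had 11 each. Bahcc1, Cdh20, Lingo2, Tmem261, 1700030C10Rik and 2410018L13Rik had 10 each, and those of Bahcc1 spanned 59.3 kb whereas those of Lingo2 spanned 2216 kb.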

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

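Settings named as added were chosen after the data had been seen. Of the 13 lists, 10 passed the threshold as deposited, and only the GABA and dopamine list kept both its direction and its side of the threshold under all 6 alternatives. With above-median peaks only (9993 peaks), 9 lists passed, and oligodendrocyte and respiration genes turned to 33.3% and 35%, against 35.4% of other genes. Counted as peaks per gene, 7 passed, and the calls of ribosomal (0.958), respiration (1) and other-organ genes (0.462, against 0.819) were lost. With genes that have any linked peak as the only background, none passed (0; Fisher's exact test, adjusted p 0.0626 to 1); fewer genes are tested there. The shares with an above-median peak, against 63.9 to 64.0% of other genes, were then 89.3% for interneuron factors, 76.9% for migration, 80% for pan-neuronal, 69.6% for progenitor, 76.5% for glutamatergic, 73.7% for ribosomal, 82.1% for chromatin and 40% for microglial and vascular genes; directions turned for astrocyte (50%), oligodendrocyte (41.7%), respiration (36.8%) and other-organ genes (75%). Matched on neighbouring genes (added), and with named genes as the background (added), 7 passed each time, and in both the pan-neuronal (80%), glutamatergic (85%) and ribosomal genes (79.2%) did not. Without dense runs, unplaced sequences and ribosomal RNA names (added; 18851 peaks), 8 passed, and glutamatergic (75%) and ribosomal genes (66.7%) lost their calls. Beyond the construction named, the cause was not tested. Merging touching peaks left 19979. Leaving out a library, another overlap, link distances and replicate agreement were not run, because the list holds 1 score per peak, no distances and no library's own peaks. Promoter windows and motifs need an mm9 annotation and sequence, which were not used here. A gene length match was not run because the lengths at hand belong to another build. No paired analysis was possible because the input has 1 library and the list holds no value per library. The unknown depth limits every statement that a gene has no peak.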

Other observations

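All gene lists and families described first here were chosen after the main data had been seen, including the scores of Jund and Egr4 and the counts of the receptor, Hox, keratin and protocadherin families; so were the tests on ribosomal and respiration genes, on above-median peaks of other factors and on ribosomal RNA peaks, whereas those on neighbouring genes, named genes, any peak of other factors, equal numbers of peaks and the Atg7 spacing were written before their results. Notch, BMP and TGF-beta, and Wnt genes were linked to Sp9 peaks more often than other coding genes. Hedgehog and cilium genes, tested as a combined list, did not pass the threshold. The pathway lists were not tested against each other, and Hedgehog genes were not tested apart from cilium genes. As background, the added lists and families had only all other coding genes. Matching on neighbouring genes, named genes as background and removal of runs, which cost some fixed lists their calls, were not applied to them. All 20 Notch pathway genes had a linked peak, with Jag2 (716.82), Rbpj (711) and Hes5 (628.96) the highest (Fisher's exact test, adjusted p = 1.73e-05 over 14 lists and families). Of these genes 17 (85%) had an above-median peak, and 3 are also in a list fixed before. BMP and TGF-beta genes had 26 of 27 linked (Fisher's exact test, adjusted p = 1.33e-05), among them Smad6 (1043.92), Bmp2 (832.85) and the BMP antagonist Nog (814.98); 20 (74.1%) had an above-median peak and 1 is also in a list fixed before. Wnt genes had 24 of 26 (Fisher's exact test, adjusted p = 0.000113), led by the feedback gene Axin2 (1696.89), and above-median peaks in 21 (80.8%). Semaphorins, plexins, ephrins and their receptors had 28 of 30 (Fisher's exact test, adjusted p = 1.73e-05), with Sema3c (1278.38) and Ephb2 (1179.14) the highest and above-median peaks in 22 (73.3%). Of these genes 3 are also in the migration and guidance list. All 20 immediate early genes were linked, 17 (85%) of them to an above-median peak, led by Jund (1734.71) and Egr4 (1698.23; Fisher's exact test, adjusted p = 1.73e-05). The Sp and KLF family had 23 of 26 linked (Fisher's exact test, adjusted p = 0.000659), led by Klf13 (1401.20), with above-median peaks in 20 (76.9%), and 6 of its genes are also in a list fixed before. Sp7, Klf8 and Klf17 had no linked peak. Hedgehog and cilium genes, with 14 of 20, did not pass the threshold (Fisher's exact test, adjusted p = 0.281), with Gas1 at 1204.98 and Ptch1 at 1056.47.

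Several gene families lay below the background. Of 1110 olfactory receptor genes, 97 (8.74%) had a linked peak, and of 355 vomeronasal receptor genes, 66 (18.6%), with exact adjusted p of 2.11e-249 and 8.01e-46 by Fisher's test. Keratins and keratin-associated proteins had 33 of 109 (30.3%; Fisher's exact test, adjusted p = 8.01e-07). Cytokines and antigen receptors had 2 of 25 (8%; Fisher's exact test, adjusted p = 4.26e-06), Il13 (203.97) and Il17a (97.97). Hox genes, which pattern the hindbrain and spinal cord, had 32 of 39 linked (82.1%; Fisher's exact test, adjusted p = 0.000699), led by Hoxd8 (657.14) and Hoxa10 (621.90), and above-median peaks in 17 (43.6%; exact adjusted p = 0.316). Clustered protocadherins had 29 of 57 linked (50.9%; Fisher's exact test, adjusted p = 0.507) and above-median peaks in 4 (7.02%; exact adjusted p = 3.48e-06). Members of these families share sequence, and how reads that match several copies were treated is not given in the sources used here. Fisher's test also counts each gene as independent, although genes of a family can be neighbours, as in the run of peaks over the Hoxd cluster.

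All 28 interneuron transcription factors had a linked peak. Lists matched on neighbouring genes averaged 67.6%, which argues against a high share of linked genes in the region as the whole cause (permutation test, two-sided p = 0.0002, the smallest these lists can give). The match was not on peaks per length of sequence, and gene length was not matched, so density by length was not tested. Against named genes only, the interneuron factors stayed past the threshold (Fisher's exact test, adjusted p = 2.35e-05), which argues against a background padded with receptor and predicted genes. For the presence of any peak, a property of regulator genes of any lineage stays open, with 31 of 34 factors of other lineages linked (Fisher's exact test against the interneuron factors, p = 0.245), and so does one of active genes in general, with 38 of 44 ribosomal and respiration genes (p = 0.0753), although the ribosomal list alone lay below them (adjusted p = 0.0375). Above-median peaks were linked to 25 of the 28 factors. This was more than in factors of other lineages (18 of 34, Fisher's exact test, p = 0.00236). It was also more than in ribosomal and respiration genes (21 of 44, Fisher's exact test, p = 0.000359), first compared among linked genes only (21 of 38, Fisher's exact test, p = 0.00318). It was not past the threshold against 5 of the 12 other fixed lists, the migration, pan-neuronal, progenitor, glutamatergic and chromatin lists (Fisher's exact test, adjusted p from 0.0628 to 0.177). Some added lists had shares nearly as high: 85% for Notch and for immediate early genes, 80.8% for Wnt and 76.9% for Sp and KLF genes. Hedgehog and cilium genes had 55%. These added lists were not tested against the interneuron factors, and peaks per gene were not compared with any added list. Part of the interneuron factors' high share cannot be told apart from their larger number of peaks per gene. Linked genes drawn with the same numbers of peaks gave 20.9 of 28 on average (permutation test, one-sided p = 0.0409). This met the criterion set beforehand, a one-sided p under 0.05, but that criterion was looser than the two-sided tests used elsewhere. The observed 25 did not lie outside the central 95% range of the draws, 16 to 25.

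Peaks named Rn45s, or for genes that the gene table classed as ribosomal RNA, held many of the highest scores. Of the 100 highest peaks, 20 were such peaks. The 31 such peaks of the list had a median score of 1566 against 209.9 for the others. Of them, 19 were named Rn4.5s, which counted as ribosomal RNA here only by its class in the gene table. Most of the 31 peaks therefore need not concern ribosomal RNA proper. The 31 peaks were wider (median 2707 bp against 985.5 bp). Among peaks at least 1259 bp wide their median was 1868 against 441.2 (permutation test, p = 0.0001, the smallest it can give, with peaks of a run treated as independent). Of these 27 peaks, 24 scored above the median of the 20 other peaks nearest in width. Chromosome 6, which held all peaks named Rn4.5s, gave 16 of the 27. With each of the 3 chromosomes counted once, their mean rank lay above 78.5 to 90% of such peaks (permutation test, one-sided p = 0.0242, a form chosen after peaks and runs had been tried as units). The names were taken up after their high scores had been seen, and 1 of the 3 chromosomes held a single such peak. The test therefore cannot decide on width as a cause. The pattern was first defined more broadly, as peaks in dense runs or with ribosomal RNA names, and was narrowed after the result because runs also cover gene-dense stretches; the broader set held 27 of the 100 highest peaks and 5.24% of the rest (Fisher's exact test, p = 1.50e-12), but among peaks at least 1259 bp wide its median was 450.6 against 441.4 (permutation test, p = 0.605). Reads of multi-copy sequence piled on few assembled copies are a candidate explanation that cannot be told apart from binding, because the list holds no copy number, mappability or input coverage, and no biological explanation was tested.

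The 33 peaks named Atg7 lay on chromosome 6 from 114476534 to 114584902 at a median spacing of 2309 bp between midpoints. If they were 1 peak in each copy of an evenly spaced tandem array, their spacing would vary little. The coefficient of variation was 0.928 against a median of 0.724 in 10000 random placements (permutation test for even spacing, one-sided p = 0.941), so no even spacing was found. Spacings ran from 591 to 16542.5 bp, whereas the random placements allowed none under 819 bp. Copies without a listed peak would also make an even array look irregular, so the test cannot exclude such an array. Irregular duplication, copy number of the CD1 animals and binding itself may each still apply and were not tested.

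Of the 7 Ttr peaks, 6 lay in 1 run with gaps under 10 kb. Over the whole list, 159 runs of 5 or more peaks with gaps under 10 kb held 1069 peaks; a run of 10 on chromosome 2 from 74493223 to 74550708 carried names of the Hoxd cluster and Evx2.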
